A study of Mus musculus with 6 samples.

How the data were processed

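RNA sequencing was carried out on 6 cultures labelled as neonatal mouse heart cells. Of these, 3 were labelled as transfected with an siRNA against Rbm22 (si-Rbm22) and 3 with a scrambled siRNA (si-Control). Per the labels' protocols, total RNA was taken with TRIzol and the libraries were made with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq, DESeq2 and the mouse build GRCm38, without versions, roles or settings. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number read counts per Ensembl gene for each of the 6 libraries, which the authors had not normalized: column totals differed, from 34269042 to 37344860. No other column of per-sample values was present, and no row stood for unassigned reads.

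Of the 18951 gene identifiers, 18856 matched GENCODE release M21, an annotation of GRCm38, from which symbols, positions, intron numbers and exonic GC content were taken. The other 95 were left unnamed and stayed in the tests. The table covered 17171 protein-coding genes and 1299 lincRNA genes. Because the counting settings are unknown, genes with near-identical processed copies, overlapping genes and antisense genes are given as uncertain. Gapdh, Gm10260 and the ribosomal protein genes are of the copied kind.

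Groups and replicate numbers came from the sample titles. The protocols call the 3 samples of a group biological replicates and do not say whether each came from its own isolation, so p-values measure the spread between these samples. Replicate counts were compared first: chi-square per degree of freedom lay between 4.52 and 7.05 among the libraries labelled si-Control and between 10.5 and 30.94 among the si-Rbm22 libraries. No pair agreed within sampling noise, and each library was counted as 1 sample.

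Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (TMM scaling, filterByExpr, robust fit, group as the only term). Genes passed at an adjusted p under 0.05, where adjusted p stands for the Benjamini-Hochberg value of this test. Values are TMM-scaled CPM, read counts relative to the scaled library total, as mean ± SD over 3 libraries. Log2 fold changes are si-Rbm22 over si-Control. The SE printed with them is the absolute log2 fold change divided by the square root of the quasi-likelihood F. It was not estimated directly. At large folds with few reads in a group it can be smaller than counting error alone. This holds for Myrf (18, 23 and 22 reads in si-Control), Tbx20 (10, 6 and 11) and Ppargc1a (9, 10 and 3), among others. A gene without reads in a whole group was set at a floor of 3 counts over that group, 0.028 CPM for the libraries labelled si-Control and 0.0272 CPM for si-Rbm22, and its fold is a lower bound. Genes with a few reads in a group have a ratio with a 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

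Before the data were examined, 35 gene lists were fixed, and lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, log2 CPM with a prior count of 2, Benjamini-Hochberg over 34 lists). An estimated correlation and fry were alternatives. The rule for the named genes was set at the same time: Rbm22, the first 10 rises and the first 10 falls by fitted fold change among genes past the test with a mean of at least 5 CPM, groups that did not overlap and a named symbol, the members of each list with the smallest p, and the 5 smallest p of each direction. Some genes that this rule named are not reported here. Genes and 7 lists chosen after the values were seen are marked as such. Relations with gene structure are Spearman correlations across genes, which are not independent replicates, and carry no p.

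The procedure was tested on simulated counts for si-Rbm22 against si-Control, with 200 changed genes among 13030. It recovered 83.6% of genes changed 1.5-fold, 98.5% of genes changed 2-fold and 100% of genes changed 4-fold, and called 0.09% of the unchanged genes. Both simulated groups were drawn from the si-Control means, and only genes with a mean of at least 1 CPM were changed. The simulation thus did not test scaling and calls where most genes differ, as in these data (82% called). Nor did it test genes without reads in a whole group. Alternatives set beforehand were RLE size factors, no filter on low counts, a filter of 10 CPM in 3 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, the mitochondrial transcripts left out, other thresholds, and the other list tests. One alternative, genes with at least 1 CPM in each library, was added after the data were seen. Leaving out the libraries whose content was in doubt was not possible, because they are all 3 libraries labelled si-Control.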

Results

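The series asked how the transcriptome of primary neonatal mouse cardiomyocytes changes when Rbm22, which encodes a zinc finger and RNA-binding protein of the spliceosome, is silenced. According to the protocols, heart muscle cells were isolated from 1-day-old C57BL/6J mice, used at a purity above 97.5% by staining for cardiac troponin T, transfected, and collected after 48 h. The data are read counts per gene for 3 libraries labelled si-Control and 3 labelled si-Rbm22. Total counts were 35955301, 35941050 and 34269042 in the libraries labelled si-Control and 37344860, 37122220 and 36860678 in the si-Rbm22 libraries. Reads fell on 15410 ± 50.8 genes in the former and 16790 ± 127 genes in the latter (SD, n = 3 each). Across genes, log2 CPM correlated at 0.9949 to 0.9954 within the libraries labelled si-Control, 0.9883 to 0.9906 within si-Rbm22, and 0.6765 to 0.6943 between the groups.

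Rbm22 mRNA was lower in all 3 si-Rbm22 libraries than in any library labelled si-Control. Rbm22 (ENSMUSG00000024604; GRCm38 chromosome 18, 60560736 to 60572810, plus strand, 10 introns) had 798, 916 and 774 reads in the libraries labelled si-Control and 533, 466 and 491 in the si-Rbm22 libraries. This was 23.2 ± 1.79 CPM against 13.5 ± 0.892 CPM (SD, n = 3 each), or 0.583 of the level in the libraries labelled si-Control (log2 fold change −0.78, SE 0.097, edgeR adjusted p = 4.22e-06). The target thus moved in the direction of the labels. A total of 3359 genes past the test fell at least as far as Rbm22.

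Transcripts of the cardiomyocyte itself were few in the libraries labelled si-Control. Myh6, the alpha myosin heavy chain of heart muscle (ENSMUSG00000040752; chromosome 14, 54941921 to 54966927), had 3, 1 and 0 reads there and 674460, 661310 and 384503 reads in the si-Rbm22 libraries. The ratio was 418600, with a 95% counting interval of 164000 to 1540000. Tnnt2, which encodes the cardiac troponin T used for the purity staining, was at 42.2 ± 2.86 CPM against 4529 ± 907.9 CPM (SD, n = 3 each; log2 fold change 6.75, SE 0.172, edgeR adjusted p = 1.17e-09). The content of the libraries labelled si-Control therefore goes against their label as cardiomyocytes. Every direction below, that of Rbm22 included, compares si-Rbm22 libraries with libraries labelled si-Control that held few of these transcripts.

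**Figure D1:**
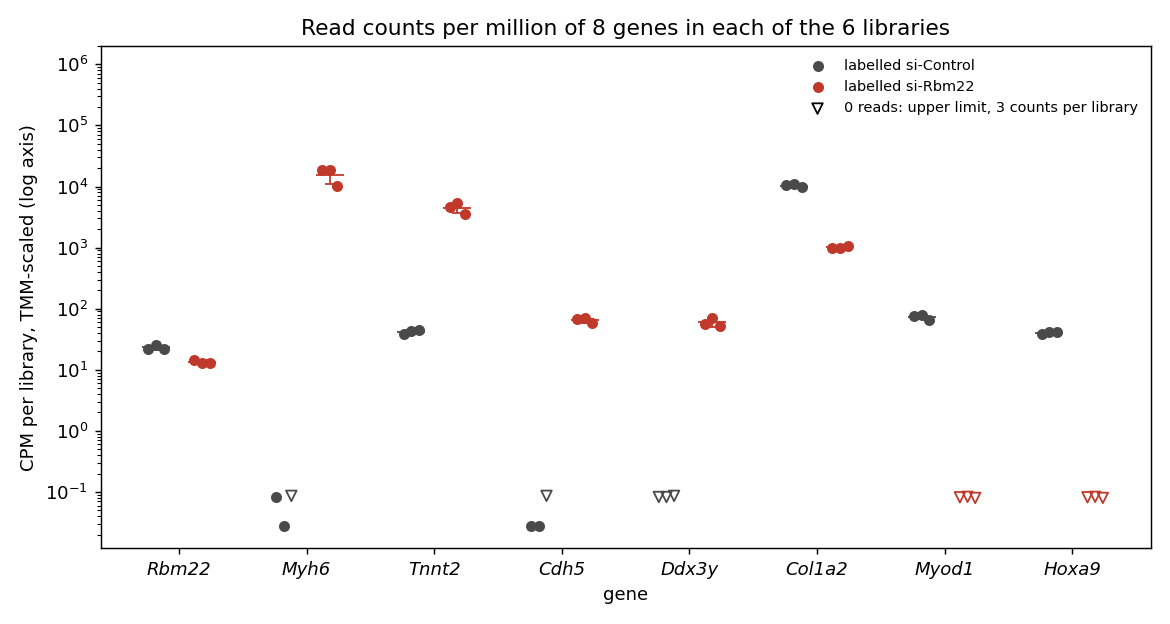
TMM-scaled CPM on a log axis for 8 genes in each of the 6 libraries, with grey points for libraries labelled si-Control, red points for si-Rbm22, bars for mean ± SD where every library of a group had reads, and open triangles for 0 reads at the upper limit of 3 counts per library. Rbm22 differed by a ratio of 0.583, whereas Myh6, Tnnt2, Cdh5 and Ddx3y were high only in the si-Rbm22 libraries plotted and Myod1 and Hoxa9 had reads only in those labelled si-Control; Ddx3y, a Y-linked gene, was chosen after its values were seen.

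Over the whole transcriptome, 11983 of 14621 tested genes (82%) differed between the groups, 6299 higher and 5684 lower in the si-Rbm22 libraries. Among these, 6301 genes changed at least 2-fold, 3566 higher and 2735 lower. Ranked by fitted fold change, which gives no exact order for genes without reads in a group, the first 10 rises were heart muscle and mesothelial genes without a single read in any library labelled si-Control, Myh6 aside. Nppa, the atrial natriuretic peptide, was at least 110800-fold higher (3108 ± 807.7 CPM in si-Rbm22, SD, n = 3). Mybpc3, cardiac myosin-binding protein C, was at least 77260-fold higher, the ventricular light chain gene Myl2 at least 43310-fold, and Pln, which encodes the calcium pump regulator phospholamban, at least 42280-fold. They were followed by the light chain genes Myl3 (at least 37090-fold) and Myl7 (at least 32060-fold). The uroplakin genes Upk3b and Upk1b, found in mesothelium, were at least 21640-fold and 12080-fold higher, and Gpm6a at least 10800-fold.

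In the same ranking, the first 10 falls included 3 genes of skeletal muscle precursors, Cdh15, Myod1 and Cacng1, and 4 posterior Hox genes. Cdh15, the cadherin of skeletal muscle precursors (chromosome 8, 122847966 to 122867397), was at 94.7 ± 7.37 CPM in the libraries labelled si-Control (SD, n = 3) and had 0 reads in si-Rbm22, at least 3483-fold lower. Myod1, the master regulator of skeletal myogenesis (chromosome 7, 46376474 to 46379099), fell from 73.4 ± 6.78 CPM to 0 reads, at least 2701-fold. The interferon-inducible gene Ifi202b was at least 2658-fold lower, and Cacng1, the gamma subunit of the skeletal muscle calcium channel, at least 1686-fold. Hoxc11, Hoxa11 and Hoxa9 were at least 1544-fold, 1507-fold and 1495-fold lower, and the X-linked homeobox gene Esx1 at least 582.5-fold. Hoxc10 and C1qtnf3 had a few reads in si-Rbm22, with si-Rbm22 over si-Control ratios of 0.000163 (counting interval 4.13e-06 to 0.00091) and 0.000224 (6.1e-05 to 0.000573).

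Ordered by p, the first genes that rose were Myrf, a transcription factor (log2 fold change 8.84, SE 0.095), Gucy1a1, Tnni3, Pkhd1l1 and Myl4. Those that fell were Islr (log2 fold change −8.94, SE 0.091), Serpinf1, which encodes pigment epithelium-derived factor (−6.52, SE 0.073), C1qtnf3, Brinp3 and Gm10260. Gm10260 is uncertain, because it can share reads with copies of the same gene. This order does not rank precision. Myrf had 18, 23 and 22 reads in si-Control, and its SE can be smaller than counting error. Gucy1a1 had 0, 1 and 1 reads there. At an unadjusted p under 0.05 the count was 12103 genes. The groups did not overlap for 12314 genes (84.2%), where chance gives 10%. Genes changed at least 2-fold numbered 3426 when only genes with 10 CPM in 3 libraries were tested, and 3092 among genes with at least 1 CPM in each library, a setting added after the data were seen.

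**Figure D2:**
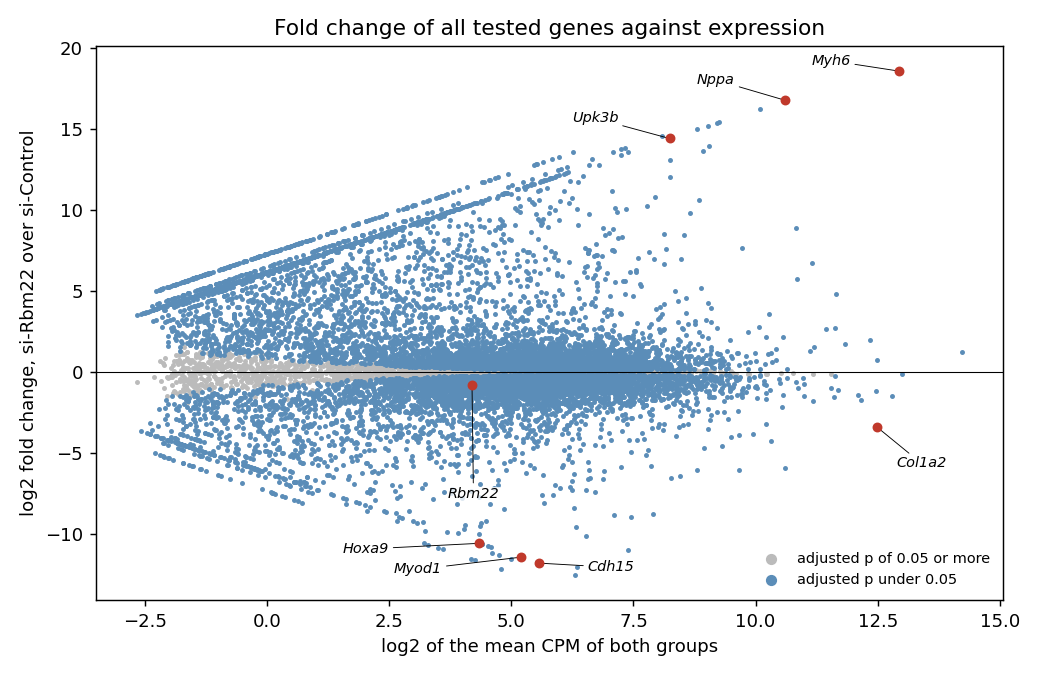
Log2 fold change (si-Rbm22 over si-Control) against the log2 mean CPM of both groups, 1 point per tested gene, blue for adjusted p under 0.05 and grey otherwise, with genes at 0 reads in one group drawn at their bound. Of 14621 genes, 11983 passed the test, and Rbm22 at −0.78 lay inside the body of the plot, far from Myh6 at 18.55 and Col1a2 at −3.36.

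Genes of the contractile apparatus, of cardiac excitation and of cardiac identity were higher in the si-Rbm22 libraries as groups. Of 28 sarcomere genes, 27 rose and 1 fell, with a median log2 fold change of 7.70. They took 0.185% ± 0.003 of reads in the libraries labelled si-Control and 4.60% ± 0.872 in si-Rbm22 (SD, n = 3 each). Tnni3, cardiac troponin I, rose from 0.579 ± 0.0475 to 923.2 ± 85.8 CPM, and the atrial and fetal light chain gene Myl4 from 5.61 ± 0.215 to 701 ± 49.9 CPM. Smpx had a ratio of 4761 (counting interval 1860 to 17500). The member that fell was Des, the muscle intermediate filament desmin (log2 fold change −0.50, SE 0.114, edgeR adjusted p = 0.00256).

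Among 26 genes for ion channels, calcium handling and gap junctions, 25 rose and 1 fell (median log2 fold change 6.38). Casq2, which binds calcium in the sarcoplasmic reticulum, rose by 6.30 on the log2 scale (SE 0.085), the sodium pump subunit gene Atp1b1 by 4.26 (SE 0.066), and the potassium channel gene Kcnj5 was at least 3035-fold higher. Kcnj2, the inward rectifier, went the other way, from 60.3 ± 3.07 to 15.1 ± 2.77 CPM. Of 24 cardiac transcription factors, 22 rose and 1 fell (median 4.72, or 4.43 with genes at 0 reads set to their bound). Gata6 rose by 6.50 (SE 0.094) and Tbx20 by 10.09 (SE 0.143), and Mef2c had a ratio of 591.3 (counting interval 374 to 998). Irx5 fell by 0.90 (SE 0.097). Fetal and stress-associated cardiac genes split, with 13 higher and 6 lower of 20. The stretch-responsive gene Ankrd1 rose by 3.59 (SE 0.069) and Tagln by 3.06 (SE 0.078).

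Adjusted over the list alone, the counts of these 4 lists were the same. By camera (BH over 34 lists) adjusted p was 3.03e-09 for sarcomere genes, 4.08e-08 for ion channel genes, 1.22e-06 for cardiac transcription factors and 0.0983 for the fetal and stress list. For the first 3, the adjusted p with an estimated correlation was 0.529.

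Endothelial, epicardial and macrophage markers were far higher in the si-Rbm22 libraries, fibroblast and matrix markers were lower, and smooth muscle and Schwann markers did not pass as lists. All 20 endothelial markers rose (median log2 fold change 7.86, or 7.57 with bounds). Their summed level was 10.8 ± 0.75 CPM in the libraries labelled si-Control and 643.9 ± 19.9 CPM in si-Rbm22 (SD, n = 3 each). Cdh5, the endothelial cadherin, had a ratio of 3488 (counting interval 965 to 28800), Tek, the angiopoietin receptor, one of 559 (327 to 1050), and Eng, a TGF-beta coreceptor gene, one of 27.8 (edgeR adjusted p = 4.41e-15). All 15 epicardial and mesothelial markers rose (median 11.18), from a summed 104.3 ± 2.17 to 3511 ± 184 CPM. Bnc1 rose by 6.75 (SE 0.085), and Lrrn4 had a ratio of 29170 (counting interval 8070 to 241000).

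Macrophage and leukocyte markers were 15 higher and 1 lower of 17 (median 6.58, or 5.50 with bounds). The cathepsin gene Ctss had a ratio of 4553 (counting interval 817 to 180000), Csf1r rose by 4.07 (SE 0.224) and Cd68 by 3.22 (SE 0.187), while Cd14 fell by 2.59 (SE 0.154). Schwann and neural markers were 6 higher and 1 lower of 7, with Mbp, a myelin protein gene, up by 7.20 (SE 0.107) and Cnp down (log2 fold change −1.86). Of smooth muscle and pericyte markers, 8 rose and 6 fell of 15, with Tagln higher and Notch3, a pericyte receptor, lower (81.1 ± 0.804 against 10.1 ± 1.25 CPM). Only 3 erythroid genes were tested. Of these, Alas2, the heme synthesis gene of red cells, rose, and Hba-a1, uncertain because of its near-identical copy, fell.

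Fibroblast and matrix markers ran the other way, with 20 lower and 4 higher of 26 (median −1.43). They took 5.77% ± 0.207 of reads in the libraries labelled si-Control and 1.65% ± 0.109 in si-Rbm22. Col1a2, a chain of type I collagen, fell from 10386 ± 454.2 to 1009 ± 39.8 CPM (log2 fold change −3.36, SE 0.064), Col6a2 by 3.87 (SE 0.074) and Col5a1 by 3.17 (SE 0.069). Tcf21, a transcription factor of cardiac fibroblasts, had 0 reads in the libraries labelled si-Control and was at least 2044-fold higher in si-Rbm22. Adjusted over the list alone, the counts of all 7 lists in these cell type groups were the same. Adjusted p by camera (BH) was 2.35e-07 for endothelial, 2.17e-07 for epicardial, 0.000219 for macrophage and 0.000299 for fibroblast markers. Adjusted p was 0.442 for the endothelial, 0.528 for the epicardial and 0.529 for the macrophage and fibroblast lists with an estimated correlation. The smooth muscle (0.593) and Schwann (0.178) lists did not pass, and the erythroid list was too short to test. The macrophage call was lost (adjusted p = 0.141) among genes with 10 CPM in 3 libraries.

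**Figure D3:**
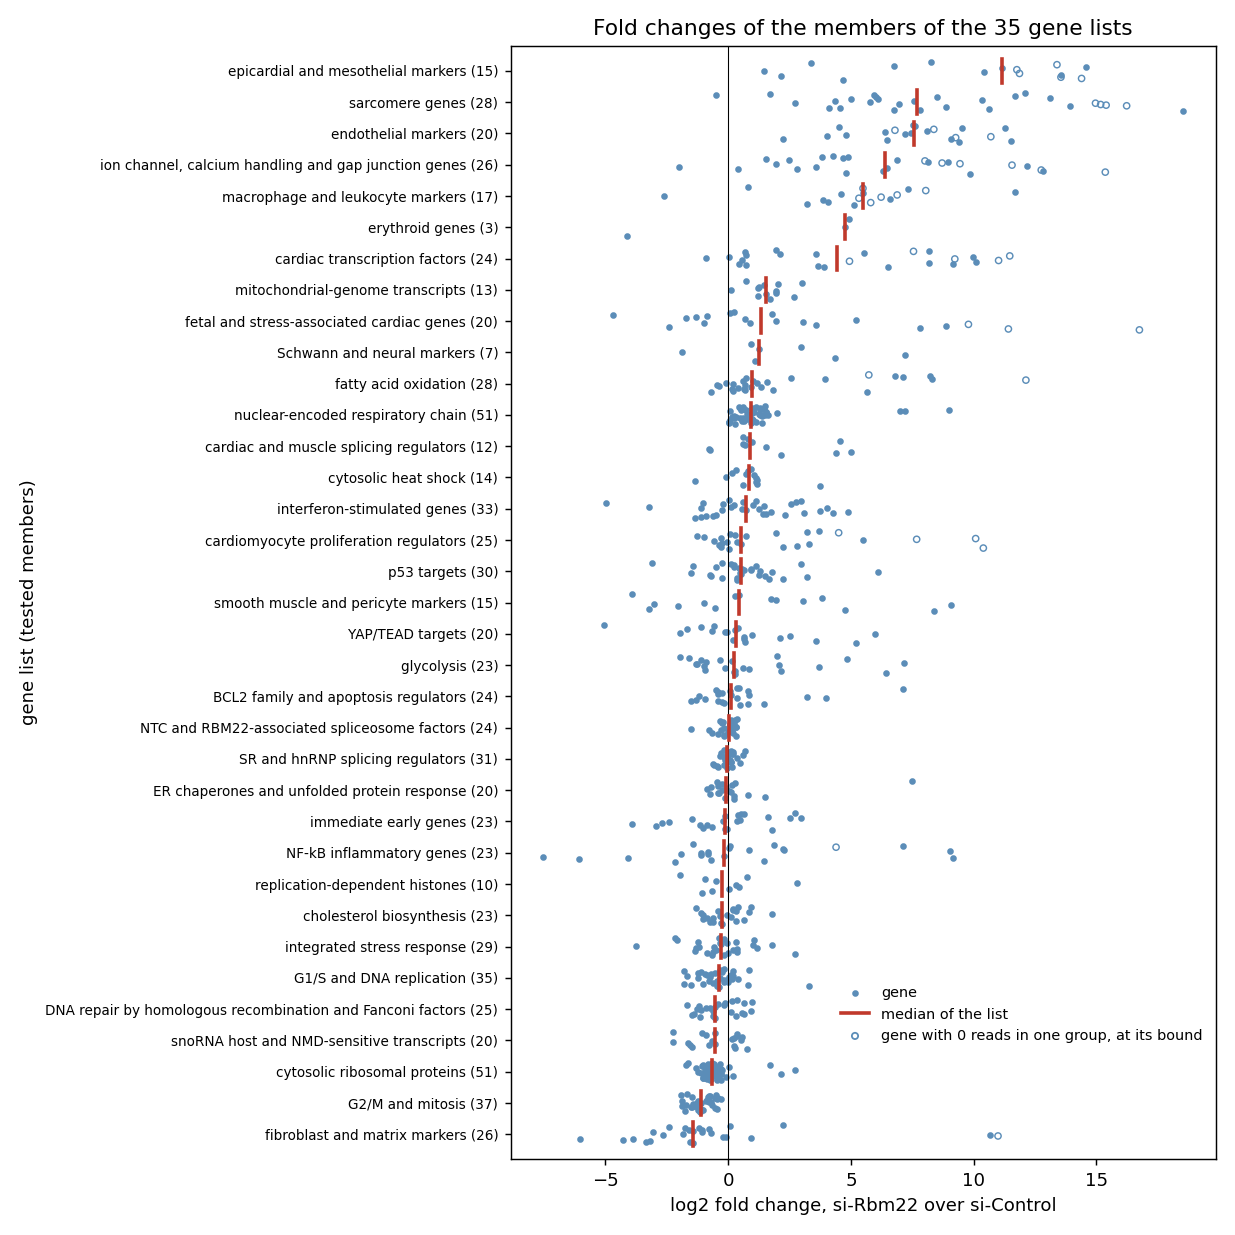
Log2 fold changes (si-Rbm22 over si-Control) of the tested members of the 35 gene lists, ordered by median, with 1 point per gene, open circles for genes at 0 reads in one group placed at their bound, and a red line for the list's median. Epicardial markers lay highest, with a median of 11.18, and fibroblast and matrix markers lowest, with −1.43.

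Spliceosome factors changed little in comparison. Among 24 partners of Rbm22 in the Prp19-associated complex and the catalytic spliceosome, 8 rose and 10 fell, with a median log2 fold change of 0.05 and a mean of −0.10, while the list test pointed down. Snw1, which sits beside Rbm22 at the active site, fell by 1.49 (SE 0.058), and Ctnnbl1 fell by 0.66 (SE 0.075). The SR and hnRNP regulators of splice site choice were 11 higher and 9 lower of 31 (median −0.04). Rbm25 rose by 0.68 (SE 0.054) and Srsf5 fell by 0.57 (SE 0.053). Splicing regulators of heart and skeletal muscle were 10 higher and 2 lower of 12 (median 0.89). Rbpms rose by 4.56 (SE 0.069), Rbm24 by 4.40 (SE 0.095) and Mbnl2 by 1.53 (SE 0.064), and Rbfox2 fell by 0.73 (SE 0.057). Sarcomere genes differed by a median of 7.70 between the same libraries. Adjusted over the list alone, the SR and hnRNP counts were 9 higher and 9 lower, and those of the other lists were the same. By camera (BH), adjusted p was 0.593 for the Prp19 complex list, 0.635 for the SR and hnRNP list and 0.023 for the muscle list, the last with 0.529 as adjusted p with an estimated correlation.

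Cell division genes were lower in the si-Rbm22 libraries. All 37 G2/M and mitosis genes fell (median log2 fold change −1.12). Racgap1, needed for cytokinesis, fell from 266.4 ± 5.95 to 83.8 ± 6.57 CPM (log2 fold change −1.67, SE 0.064), Ccnb2, a mitotic cyclin, by 1.75 (SE 0.076) and the midzone kinesin gene Kif23 by 1.43 (SE 0.059). Of 35 G1/S and replication genes, 20 fell and 5 rose (median −0.39). E2f1 fell from 44.7 ± 3.96 to 15.8 ± 1.35 CPM, Rfc3 by 1.22 on the log2 scale (SE 0.088) and Uhrf1 by 1.09 (SE 0.073), whereas the cyclin gene Ccnd2 rose by 3.31 (SE 0.066). Homologous recombination and Fanconi genes were 14 lower and 8 higher of 25, with Rad54b down (log2 fold change −1.39, SE 0.120) and Atm, the damage kinase, up by 0.98 (SE 0.082).

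Targets of p53 were 21 higher and 8 lower of 30 (median 0.52), with Perp up by 6.10 (SE 0.074) and Ccng1 by 2.23 (SE 0.059). BCL2 family and apoptosis regulators were 11 higher and 11 lower of 24, with Pmaip1 up by 3.22 (SE 0.117) and Birc3 at a ratio of 143.4 (counting interval 81.9 to 278). Regulators of cardiomyocyte proliferation were 15 higher and 7 lower of 25 (median 0.54), with the smallest p for Ccnd2 and for Dusp6, which rose by 3.70 (SE 0.078). The libraries compared for these genes were those with 0.185% and 4.60% of reads on sarcomere genes. Counts adjusted over the list alone were the same for these lists. By camera (BH), adjusted p was 4.08e-08 for G2/M and 0.0198 for G1/S, and 0.529 and 0.803 as adjusted p with an estimated correlation. The G1/S call was lost without si-Rbm22 replicate 2 (adjusted p = 0.0559) and among genes with at least 1 CPM in each library (0.0676). DNA repair (0.138), p53 targets (0.0551), the apoptosis list (0.808) and the proliferation list (0.0551) did not pass. By camera, the p53 list passed in 4 alternatives, at 0.00847 to 0.0486, and the proliferation list in 2, at 0.0468 and 0.0486. Both passed by fry, at 3.14e-05 and 2e-06.

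Genes of oxidative metabolism were higher in the si-Rbm22 libraries. Of 51 nuclear-encoded respiratory chain genes, 45 rose and 0 fell (median log2 fold change 0.94). Atp5o, an ATP synthase subunit gene, rose by 1.49 (SE 0.069). Cox7a1, a muscle isoform, rose by 7.02 (SE 0.177), and Cox8b, another, had a ratio of 564.6 (counting interval 220 to 2070). Among 13 transcripts of the mitochondrial genome, 12 rose and 0 fell (median 1.53), with the smallest p for mt-Nd2 (2.68, SE 0.070), mt-Nd5 (1.96, SE 0.061) and mt-Nd1 (1.72, SE 0.074). They took 2.20% ± 0.134 of reads in the libraries labelled si-Control and 5.57% ± 0.206 in si-Rbm22 (SD, n = 3 each). Fatty acid oxidation genes were 24 higher and 3 lower of 28 (median 0.99). The coactivator gene Ppargc1a rose by 8.22 (SE 0.160), Fabp3, the heart fatty acid binding protein gene, by 8.30 (SE 0.162) and Acadl by 1.82 (SE 0.071), and Cpt1a, the liver-type carnitine transferase gene, fell by 0.69 (SE 0.060).

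Glycolysis genes split, 12 higher and 9 lower of 23, with the muscle isoform gene Pgam2 up by 7.17 (SE 0.163). Gapdh was at 79.2 ± 2.83 against 337.6 ± 37.6 CPM, but this value is uncertain, as many processed copies can take its reads. Cholesterol synthesis genes were 9 higher and 12 lower of 23, with Srebf2 down (log2 fold change −1.29, SE 0.065) and Hsd17b7 up by 1.77 (SE 0.077). Sarcomere genes moved with the rising groups, with a median of 7.70. The counts of these 5 lists were the same adjusted over the list alone. Adjusted p by camera (BH) was 7.63e-07 for the respiratory chain, 0.00269 for the mitochondrial genome and 0.0009 for fatty acid oxidation, but 0.638, 0.529 and 0.529 with an estimated correlation. Glycolysis (0.808) and cholesterol synthesis (0.38) did not pass.

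Ribosomal protein genes fell and cytosolic heat shock genes rose. Of 51 ribosomal protein genes, 45 fell and 4 rose (median −0.66), with Rps20 (log2 fold change −1.73, SE 0.075) and Rpl37 (−1.23, SE 0.055) lower and Rps2 higher (2.71, SE 0.060). Values of this family are uncertain because of its many processed copies. Of 14 heat shock genes, 12 rose and 1 fell (median 0.87). The constitutive chaperone gene Hspa8 rose by 1.16 (SE 0.056), Dnaja1 by 1.18 (SE 0.062) and Hspb1 by 1.05 (SE 0.058), and Dnajb1 fell by 1.34 (SE 0.060). By camera (BH), adjusted p was 3.04e-07 for ribosomal proteins and 0.0288 for heat shock, each with 0.529 as adjusted p with an estimated correlation.

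Stress and inflammatory programmes were mixed. Integrated stress response genes were 9 higher and 16 lower of 29, with Ddit4 down (log2 fold change −2.08, SE 0.060) and Gdf15 up by 1.78 (SE 0.083). Endoplasmic reticulum chaperones were 7 higher and 9 lower of 20 (median −0.10, mean with bounds 0.32), with Dnajb9 up by 1.52 (SE 0.077) and Calr down (−0.88, SE 0.055). Immediate early genes were 10 higher and 10 lower of 23, with Junb (−2.96, SE 0.085) and Egr2 (−3.91, SE 0.138) lower. Interferon-stimulated genes were 18 higher and 4 lower of 33 (17 higher and 4 lower adjusted over the list alone). Their smallest p belonged to members that fell, Ifi203 (−4.96, SE 0.157) and Ifit2 (−0.91, SE 0.084). NF-kB genes were 9 higher and 11 lower of 23 (median −0.15, mean with bounds 0.46), with the chemokine gene Cxcl5 lower (−7.54, SE 0.108).

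YAP/TEAD targets were 12 higher and 6 lower of 20, with Ankrd1 and Wwc1 higher (Wwc1 by 5.98, SE 0.134). Of 10 replication-dependent histone genes, 2 rose and 2 fell, with Hist1h1c lower (−1.06, SE 0.054) and Hist1h4h higher (2.81, SE 0.502). Hosts of small nucleolar RNAs and transcripts tied to nonsense-mediated decay were 7 higher and 11 lower of 20 (median −0.53), with Zfas1 (−2.26, SE 0.082) and Gadd45g (−2.24, SE 0.064) lower. Among the ribosomal, heat shock, stress, inflammatory, YAP/TEAD, histone and small nucleolar RNA host lists, only the interferon-stimulated genes had other counts adjusted over the list alone. Macrophage markers, with a median of 6.58, and sarcomere genes, with 7.70, moved between the same libraries. None of these 8 lists passed camera (BH adjusted p 0.171 for the integrated stress response, 0.593 for the chaperones, immediate early and NF-kB genes, 0.474 for interferon, 0.455 for YAP/TEAD, 0.554 for histones and 0.239 for the small nucleolar RNA hosts).

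Because Rbm22 belongs to the spliceosome, fold changes were compared with gene structure. Genes without introns had a median log2 fold change of 0.11 (456 genes) and genes with over 20 introns one of 0.14 (1751 genes). The Spearman correlation of fold change with the number of introns was 0.031 over 14582 genes, and 0.038, 0.039 and 0.018 for the 3 si-Rbm22 libraries against the mean of those labelled si-Control. Gene length had a larger correlation, 0.137. The 981 shortest genes, under 3.2 kb, had a median of −0.26, and the 2038 genes over 100 kb one of 0.44 ± 0.049 (SD over the 3 si-Rbm22 libraries). Exon length correlated at 0.099 and exonic GC content at −0.135. These are correlations across genes, and genes are not independent replicates. Counts per gene do not measure splicing, and cell content differed between the groups. The values therefore cannot show whether loss of Rbm22 acts by intron number.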

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

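The setting with at least 1 CPM in each library was chosen only after the data were seen; all others were planned. Genes changed numbered between 8772 and 13057 over all settings and between 11773 and 12315 with 1 library left out. Genes changed at least 2-fold numbered 3426 with a filter of 10 CPM in 3 libraries and 3092 with at least 1 CPM in each library, where fewer genes were tested, and between 6405 and 6554 with 1 library left out. Rbm22 mRNA stayed lower and past the threshold in every setting, with log2 fold changes of −0.84 to −0.73. Of 117 other named genes, all 1586 values under the alternatives that tested them kept their direction and side of the threshold. These genes were named mostly by small p or large fold in the same data, so this stability was largely set by their choice. Gene lists tested by camera with a preset correlation gave 15 calls, and 14 to 17 with 1 library left out; with an estimated correlation the count was 0 (lowest unadjusted p 0.013, 2 lists under an unadjusted 0.05), and by fry, which asks whether a list's genes move one way without comparing them with other genes, 31. The cause of the difference from camera was not tested beyond these tests' construction. Without the mitochondrial transcripts 14 lists were called, since that list was then absent. Same-numbered libraries of the 2 groups did not deviate together (correlations −0.016, 0.007 and 0.008), so no pairing by number was seen. A shared isolation cannot be excluded in this way, because the groups differed in cell content. With the replicate number as a block 11945 genes were called. In genes with a mean of at least 10 CPM the correlation of fold change with GC content moved from −0.135 to −0.205, with exon length from 0.099 to 0.145, with gene length from 0.137 to 0.14 and with intron number from 0.031 to 0.034, so GC content rather than gene length then had the largest; the cause was not tested. The effect of depth was not tested by down-sampling; genes at 0 reads in a group have only a bound, set by the floor of 3 counts.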

Other observations

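The genes and lists in the next 2 paragraphs, the Y-linked, cell type marker and mesenchyme tests of the si-Control content and both tests of replicate 3 were chosen only after the results were seen. The 4 ubiquitous Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 reads in every library labelled si-Control and 14569 reads in all over the si-Rbm22 libraries. Ddx3y was at 60 ± 9.55 CPM there (SD, n = 3) and Uty at 15.9 ± 2.00 CPM. Xist, the X inactivation transcript, was found in both groups, at 1017 ± 43 CPM in the libraries labelled si-Control and 293.6 ± 47.4 CPM in si-Rbm22. The 9 Hox genes examined, from the A and C clusters, had 33000 reads in the libraries labelled si-Control and 9 in si-Rbm22. Chrna1, the muscle acetylcholine receptor gene and the most abundant of 8 skeletal myogenic genes seen among the falls, was at 336.9 ± 7.47 CPM in the libraries labelled si-Control and 0.166 ± 0.241 CPM in si-Rbm22.

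Of 18 tested imprinted genes, 16 were higher in si-Rbm22 and 1 lower. The one that fell was H19, the noncoding RNA beside Igf2, from 3057 ± 80.4 to 50.7 ± 13.2 CPM (log2 fold change −5.91, SE 0.194, edgeR adjusted p = 4.13e-08). Meg3, Rian and Dlk1 of the Dlk1 cluster had 0 reads in the libraries labelled si-Control and were at least 5118-fold, 4947-fold and 1078-fold higher. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, also had 0 reads there and were at least 205.4-fold and 1087-fold higher in si-Rbm22. Their neighbour Mtap was at 108.6 ± 2.48 CPM in the libraries labelled si-Control and 98.1 ± 11.8 CPM in si-Rbm22. On chromosome 15 the median log2 fold change of 592 genes was −0.54, while the medians of the other autosomes lay between −0.12 and 0.26.

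The libraries labelled si-Control held few cardiomyocyte transcripts, and the data argue against an siRNA effect on, or outgrowth of other cells in, parts of one culture, since each Y-linked gene had at least 512 reads in every si-Rbm22 library and 0 in the others. In cultures of separate hearts, outgrowth of endothelial or epicardial cells is argued against by their markers, lower in the libraries labelled si-Control (summed 10.8 against 643.9 CPM and 104.3 against 3511 CPM). Outgrowth of fibroblasts there stays open, as fibroblast and matrix markers were higher (57110 against 16690 CPM) but mesenchyme factors were mostly lower. Of 12 such factors, 1 was higher in si-Control (median ratio 0.00722), though 7 of the 12 also mark cardiomyocytes. The other 5, a choice narrowed after their values were seen, had a median ratio, si-Control over si-Rbm22, of 0.0393 (Wt1). Tcf21 and Gata5 had ratios of 0 and Tbx18 one of 0.367. Only Isl1 was higher, with a ratio of 5.65 at a low level (2.2 against 0.39 CPM). Fibroblast outgrowth alone would leave unexplained the reads of the 8 myogenic genes seen among the falls, 83930 in si-Control against 84. It would also have had to leave 3, 1 and 0 Myh6 reads 48 h after transfection, from cells of a stated purity above 97.5%. Cells of another source, skeletal myoblast-like, may account for these libraries and stay open. Of 8 myogenic genes not looked at before, 4 were at 1 CPM or more there and under it in si-Rbm22. So were 3.42% of tested genes and all 8 myogenic genes that had raised the idea. The prediction had asked for most of the 8 not looked at before, so this did not decide it. By the gene-wise test, 7 of those 8 were tested, and 6 were lower and 1 higher in si-Rbm22. Among all 14621 tested genes, 5684 were lower. The purity staining describes the isolated heart cells and cannot exclude cells of another source under this label. Another strain also stays open. Nnt, partly deleted in C57BL/6J, had a ratio of 0.377, where another strain predicted a higher level. This value lay in the range set beforehand for no other strain. It was left undecided because respiratory chain genes moved the same way, by a median log2 of 0.94 against 1.41 for Nnt. Ifi202b, the other of 2 genes chosen as C57BL/6J strain genes and one of the first 10 falls, had reads in the libraries labelled si-Control alone (2549, 2665 and 2549). No prediction was written for it, so it did not enter this verdict. An exchange of samples before sequencing was not tested.

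Rbm22 was lower in the si-Rbm22 libraries, by a difference that could come from the siRNA or from cell type alone. Against 55 other splicing factors, with a mean log2 fold change of −0.05 and an SD of 0.36, Rbm22 lay −2.004 SD from the mean, and 2 factors fell as far. The predictions had asked for less than 2 SD if cell type sufficed and more than 5 SD if not, so the sources cannot be told apart with this design, in which cell content and siRNA change together.

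Replicate 3 of si-Rbm22 had fewer sarcomere reads than replicates 1 and 2, with a median ratio of 0.743 over 28 genes. Reads of the libraries labelled si-Control mixed into it are argued against: the drop needs 25.7% of such material, while 321 genes at least 10-fold higher in those libraries than in replicates 1 and 2 gave a median share of 0.204%, the highest 8.58%. This test replaced one on Fn1, which was no higher in replicate 3 (3766 CPM) than in replicates 1 and 2 (3848 CPM) and gave no share, and one on the 9 Hox genes, which had been chosen for their near absence from si-Rbm22. A larger share of stromal cells stays open as a candidate explanation, with a median ratio of 1.148 for fibroblast and matrix markers (21 of 24 above 1), although endothelial markers stood at 0.892, G2/M genes at 1.178 and interferon-stimulated genes, the lowest list, at 0.723 (1 of 19 above 1). The labels name no difference between these 3 libraries.

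Regrouping the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. Every split but the real one mixes libraries of both groups on each side. The large group difference then enters the spread within each side, and part of it remains between the sides. For genes changed, 1 split, the real one, reached 11983, and the highest other gave 0. The same held for genes changed at least 2-fold, where 1 split reached 6301 and the highest other gave 0. For gene lists called by camera with a preset correlation, 7 splits gave at least the 15 of the real one, and the highest other gave 18. Because of this mixing, neither the gene counts nor the list counts can show whether the real grouping stands apart.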
